A study of Drosophila melanogaster with 6 samples.

How the data were processed

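RNA was measured in astrocytes sorted from brains of Drosophila melanogaster at the third larval instar (L3, 2 libraries) and in adults (4 libraries). Astrocytes carried Alrm-Gal4, a driver named for an astrocyte gene, with a red fluorescent UAS-RedStinger reporter and a membrane-bound GFP reporter. Per the labels' protocols, brains were treated with collagenase and dispase at 29 °C for 15 min (larval) or 30 min (adult), so enzyme time differed with stage. Pools of 1000 red cells were sorted for each library, and polyadenylated RNA was turned into 3′ end libraries with a MARS-seq derivative, in which barcoded cDNA is amplified by in vitro transcription before sequencing.

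The deposited table gives whole-number counts per gene symbol for 16666 symbols and 6 libraries, without normalization, and no library was pooled with another. Per the submitters' processing notes, bcl2fastq, HISAT 0.1.5 and HOMER were used. Their role, the genome build, the annotation and whether molecular identifiers were collapsed are not given in the sources used here. Intervals and floors therefore cover counting error only. All 6 sample columns were used, and 0 others were present. Of the symbols, 12618 were current and 3896 were synonyms in a RefSeq gene table of assembly Release 6 plus ISO1 MT, and 152 had no match. That table served only for names and for which genes neighbour each other. No coordinates are given, because the build of the deposited table is not known.

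Levels are given as CPM, the deposited count of a gene scaled to its library's total count in the usual CPM unit. The main test was edgeR 4.0.16 quasi-likelihood in R 4.3.3, with TMM scaling, the filterByExpr filter by stage, 1 coefficient for stage and Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of genes in the text come from this test unless another tool is named. A log2 fold change is adult minus L3. Its standard error (SE) was derived as its absolute value divided by the square root of the test's F statistic, so it is approximate. For a gene with no count in 1 stage, the fold was bounded with a floor of 3 counts over that stage, equal to 0.657 CPM in L3 and 0.724 CPM in adult. For a gene with 1 to 3 counts in a stage, the pooled-count ratio is given with its 95% counting interval. It divides the counts summed over each stage by the summed library totals, so it differs from the ratio of the mean CPM values.

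Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 3) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. The lists comprised 11 sets of cell type markers and 21 functional sets. The list of mitochondrial genome transcripts had 0 members in the table. The members fabp, magro, dl and takeout had no match.

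The groups, the main test, the lists, most of the other settings and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and the 8 largest falls among genes past 0.05 whose stages did not overlap, with a mean of at least 50 CPM in the higher stage and a given name. It added the member of each functional list with the smallest adjusted p in each direction, up to 2 more where a list had 5 or more calls, and alrm, Eaat1, Gat, repo and the most abundant member of each marker list. A gene outside this rule is given as an example of its list and was chosen after its values were seen. A few genes that meet the rule or belong to a list are not reported here.

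Other settings chosen at that point were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, robust dispersion, no filter and a stricter filter on low counts, thinning every library to the shallowest, leaving out each library in turn, a replicate block on the 4 libraries that share numbers, and a threshold of 0.01. After the data were seen, edgeR's earlier quasi-likelihood method was added, with 1 row per group of neighbouring genes that share counts, both together, and the 4 libraries of the block fit without the block.

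Genes were said to share counts where symbols at most 10 rows apart in the table, each with at least 30 counts, differed by under 5% of their summed counts over the 6 libraries. Distant genes, more than 10 rows apart, were compared where both had at least 200.0 counts. They were said to share counts where the chi-square of their counts over the 6 libraries was under 0.3, a closeness that counting noise alone rarely gives. The row numbers serve only as the order of the table.

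The tests were checked on simulated data with the means and totals of these libraries. In 10 simulations with 200.0 changed genes among a median of 8371, edgeR recovered 1.4%, 24.8%, 47.2% and 71.0% of genes changed 2-, 4-, 8- and 16-fold. Of its calls, 13.4% were unchanged genes, against 4.82% with the earlier quasi-likelihood method and 3.93% with limma-voom. In the same simulations 9.49% of unchanged genes had an unadjusted p under 0.05, so the main counts may hold more chance calls than the threshold states. DESeq2, run on 9082 genes, recovered 4%, 32.2%, 56.2% and 76.8%, and 31.1% of its calls were unchanged genes. Camera called a list of 40.0 genes raised 2-fold in 10 of 10 simulations, camera with an estimated correlation in 2 and fry in 7. Of 200.0 unchanged lists they called 1, 0 and 0. Both stages were simulated with the same spread per gene, whereas in the data it was 45.1% in L3 and 79.9% in adult. Only 200.0 genes were changed, whereas 2064 of 9082 were called in the data, so the share of chance calls there may differ. Genes were drawn independently of each other in these simulations, so the rates do not cover lists whose members vary together. In the data, the estimated correlation was 0.523 for ribosomal proteins, 0.301 for clock genes and 0.240 for the respiratory chain. The search for shared counts found 197 of 197 planted neighbouring pairs with 1 other pair among 9900.0 simulated rows, and 50.0 of 50.0 planted distant pairs with 1 other.

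Library totals ran from 745129 to 2641671 counts, and both L3 libraries were deeper than every adult library. Chi-square values per degree of freedom between replicate libraries were 11.2 to 20.7, so no pair agreed within sampling noise and each library counted once. The labels do not say that the pools came from separate animals or days, so p-values measure the spread between sorted pools, which may be technical. Labels give no batch or sequencing date.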

Results

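Astrocytes are the glia that infiltrate the synaptic neuropil of the fly brain. The series profiled them before neuronal remodelling, in L3 larvae, and after it, in adults, and its title concerns actin-dependent infiltration by astrocytes as axons defasciculate. The L3 libraries held 2641671 and 1923097 counts, with 11687 and 11988 genes detected. The 4 adult libraries held 1197694, 745129, 912479 and 1287871 counts, with 9541, 8542, 9024 and 10403 genes detected. The 10 top genes took 6.42% and 6.40% of L3 counts and 13.4% to 19.3% of adult counts. Correlations of log2 CPM between libraries were 0.892 within L3, 0.726 to 0.807 within adult and 0.557 to 0.669 between stages. The coefficient of variation between replicates was 45.1% in L3 and 79.9% in adult.

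In adult astrocytes 21 of 29 transmitter and ion handling genes and 4 of 11 clock genes were higher, and 53 of 86 ribosomal protein genes, 13 of 35 cell cycle genes and 10 of 22 heat shock genes were lower. Camera called all 5 of these lists, and none with an estimated correlation (adjusted p = 0.366, and 0.564 for ribosomal proteins). The GABA transporter Gat rose from 245 ± 289 CPM (SD, n = 2) to 2151 ± 895 (SD, n = 4), with L3 libraries at 40.9 and 450 CPM. The collagen IV gene Cg25C rose from 27.1 ± 9.45 to 1525 ± 208 CPM, and the clock gene tim rose from 1.54 ± 0.0324 to 407 ± 93.2. The small heat shock gene Hsp23 fell from 957 ± 118 to 22.9 ± 19.9 CPM, and the ecdysone-inducible gene ImpE1 fell from 724 to 14. The astrocyte gene alrm, whose driver marked the sorted cells, was at 1103 ± 343 CPM in L3 and 1305 ± 264 in adult, a difference within the replicate spread (log2 fold change 0.24, SE 0.31, adjusted p = 0.634).

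Of 9082 genes tested with edgeR, 876 were higher and 1188 lower in adult, and 873 and 1162 of these changed at least 2-fold. The median log2 fold change over all tested genes was -0.14. Higher calls were 42.4% of all calls, against 53.0% with DESeq2, which called 760.0 genes higher and 673 lower. Stages did not overlap in 37.7% of tested genes, where chance gives 13.3%, and 1975 of the 2064 called genes were among them. The counts were 403 higher and 509 lower without L3 library 1, a fit in which the remaining L3 library is assumed to vary like the adult ones. With the earlier quasi-likelihood method they were 521 and 558.

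**Figure D1:**
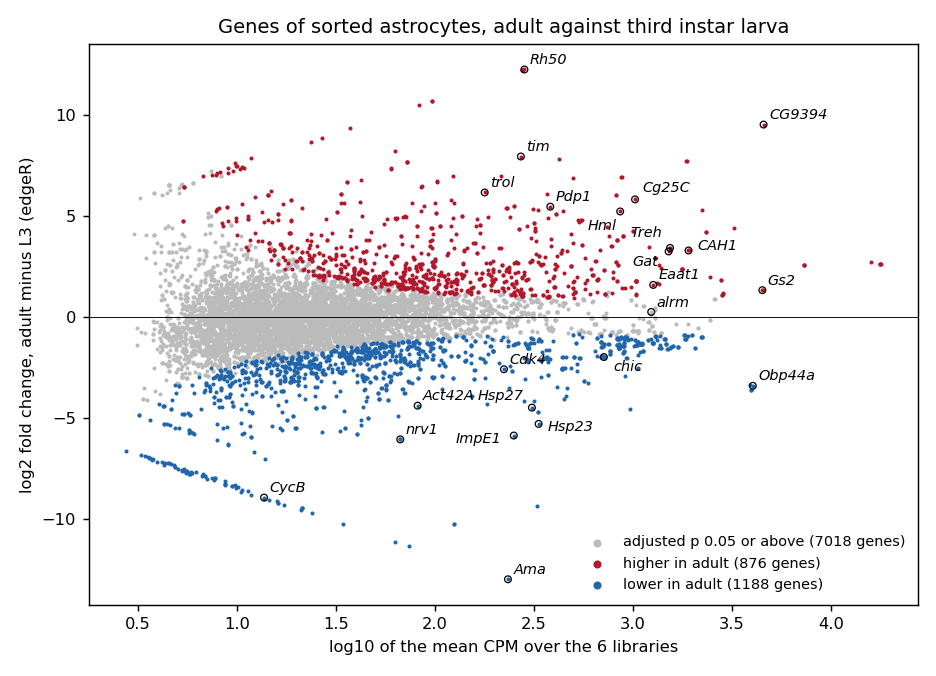
Log2 fold change (adult minus L3) of each of the 9082 tested genes against the log10 of its mean CPM over the 6 libraries. Red points are the 876 genes higher in adult and blue points the 1188 lower, grey points did not pass, and the diagonal band of points at low mean CPM holds genes with no count in 1 stage.

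Counts of neighbouring genes were often the same, so a call often belongs to a group of neighbours and not to 1 gene. Of 9900.0 genes with at least 30 counts, 5789 (58.5%) lay in 2475 groups with near-identical counts, the largest of 12 genes. Such groups held 1250.0 of the 2064 called genes (60.6%). With 1 row kept per group, 6032 rows were tested and 542 were higher and 716 lower. The rows left out held 45.5% to 50.3% of each library's total count. Library totals and the CPM scale therefore include repeated counts. The group of sinu, Sucb, Msr-110 and snmRNA:357 had 3460.0 and 4557 CPM in L3 and 17867 to 31058 in adult. The group of coil, Pbp49, Pabp2 and Obp44a had 10529 and 9773 CPM in L3 and 704 to 1235 in adult. Which gene of a group the RNA came from cannot be told from the counts.

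Some genes far apart in the table also had the same counts. Among 4959 of the more abundant genes, 159 distant pairs agreed more closely than counting noise, where about 7.33 were expected by chance. These pairs held 257 genes, of which 105 were called. Orc2, a replication origin gene, formed such a pair with snoRNA:Or-aca3, a neighbour of the ribosomal protein gene RpL4 that shared its counts. Orc2 and RpL4, compared after their values were seen, differed by 0.35% of their summed counts. A gene whose counts are shared is given below with a gene that has the same or nearly the same counts, or is said to have neighbours' counts, and its values could belong to any of them. Looser likeness between neighbours, under 30% of summed counts, was found for Gdh and RpS19b, kek1 and Vha68-2, and Hsp23 and Hsp27, so their falls may not be separate. It was also found, each with other neighbours, for Gat, Inx2, nSyb, Pen, Mtl, br, Ras85D, sty, dally, Cdk1, ATPsynbetaL, Pepck, Hex-A, bmm, Hsp67Ba, E(spl)malpha-BFM and E(spl)mgamma-HLH. Looser likeness between distant genes was not searched for, and the percentages given below for wun2, RhoGEF64C, PGRP-SC1a and Hsp23 are of pairs chosen after their values were seen.

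**Figure D2:**
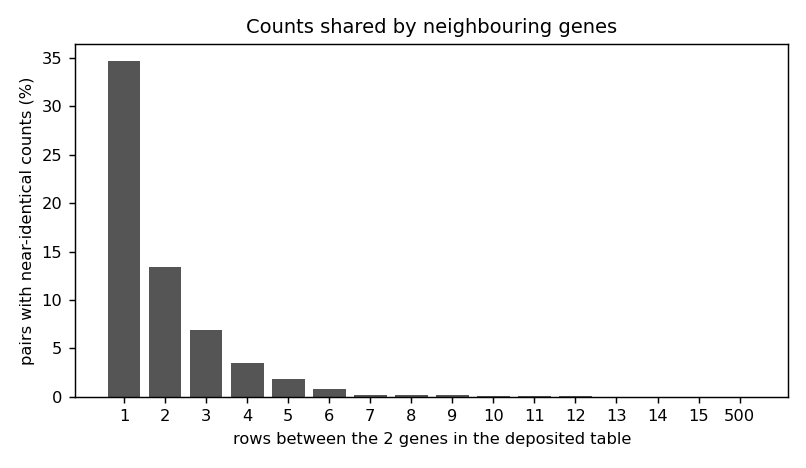
Percent of gene pairs with near-identical counts over the 6 libraries against how many rows apart they stand in the table, for genes with at least 30 counts each. Adjacent genes were near-identical in 34.7% of pairs and genes 5 rows apart in 1.84%.

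The largest rises included genes with no count in either L3 library. Rh50, an ammonium transporter of the Rhesus family, reached 425 ± 68.6 CPM in adult, at least 647-fold higher (adjusted p = 4.37e-08). Timp, an inhibitor of matrix metalloproteinases, reached 56.1 CPM, at least 85.4-fold higher (adjusted p = 0.000103). The UDP-glycosyltransferases Ugt35b, Ugt86Dg and Ugt86De shared counts and reached 417 CPM for Ugt35b, at least 635-fold higher. Amph, a membrane-bending protein, rose from 2.91 to 635 CPM (log2 fold change 7.84, SE 0.71). GlcAT-P, which shared counts with neighbours, rose from 0.520 to 109 CPM, a pooled-count ratio of 256 with a counting interval of 70.5 to 2121.

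The largest falls included genes with no count in any adult library. Ama, an immunoglobulin-family adhesion molecule, was at 702 ± 23.1 CPM in L3, and its adult value was at least 969.9-fold lower (adjusted p = 1.43e-08). betaTub60D, a tubulin, fell from 103 CPM, at least 142-fold. Pen, an importin, fell from 71.9 CPM, at least 99.2-fold, and Taf12L from 52.0 CPM, at least 71.9-fold. The L3 libraries had 75.0 and 29.1 CPM of Taf12L, so its bound leans on L3 library 1. ppk30 and Obp99a shared counts and fell from 374 to 0.194 CPM, a pooled-count ratio of 1636 with a counting interval of 293 to 64673. The sodium pump subunit nrv1, which shared counts with CG17378, fell from 196 to 2.42 CPM (log2 fold change -6.07, SE 0.63).

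The marker lists compared the cells with other types that a brain sort could hold. Of 9 astrocyte markers, 6 rose and 1 fell (6 and 1 adjusted over the list alone). Eaat1, a glutamate transporter, rose from 539 ± 86.1 to 1632 ± 623 CPM (log2 fold change 1.58, SE 0.37, adjusted p = 0.0034). Gs2, a glutamine synthetase that shared counts with Evi5, rose from 2250.0 to 5635 CPM. Dat, a dopamine N-acetyltransferase with the same counts as DnaJ-60, rose from 25.2 to 470.4 CPM. The lipid phosphatase gene wun2 fell from 116 to 8.61 CPM, and its counts differed from those of the distant gene CG15097 by 9.97% of their sum. The list was higher with camera (adjusted p = 0.00282, and adjusted p = 0.366 with an estimated correlation).

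Of 5 pan-glial markers, 2 rose and 0 fell (2 and 2 adjusted over the list alone): the glial transcription factor repo, which shared counts with CG7156, went from 227 to 632 CPM, and the sodium pump subunit nrv2 from 350.4 to 1915. The list's median log2 fold change was -0.21, its mean 0.28 and its camera direction up (adjusted p = 0.561, and 0.635 with an estimated correlation). 1 member fell when adult library 1 was left out. Eaat2 rose among 3 ensheathing glia markers (1 adjusted over the list alone), and zyd and ana among 4 cortex glia markers (2 adjusted over the list alone). Those counts were 0 and 0 without L3 library 1. The ensheathing count was 0 without adult library 4, and without L3 library 2 or adult library 1 the cortex count was 1. The most abundant of these markers did not pass: CG9657 had 54.2 and 72.3 CPM, with the same counts as CG14411, and Cyp4g15 had 202 and 302 CPM. Of 6 surface glia markers, 1 fell (1 adjusted over the list alone), Indy, which shared counts with Cat, and this call was lost without L3 library 1 or adult library 1. Tret1-1 was at 30.5 and 62.4 CPM (adjusted p = 0.185). Camera gave the surface list an adjusted p of 0.519, and 0.608 with an estimated correlation.

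Of 14 neuron markers, 3 rose and 0 fell (8 and 0 adjusted over the list alone). The synaptic vesicle gene nSyb rose from 7.71 ± 8.22 to 53.5 ± 17.4 CPM, and Ddc and Gad1 rose, each sharing counts with neighbours. The pan-neuronal gene elav was at 65.3 and 100.2 CPM (adjusted p = 0.284). Camera gave the list an adjusted p of 0.00269, and adjusted p = 0.366 with an estimated correlation. With L3 library 1 left out, the list's median log2 fold change was 1.49, against 1.67 with all libraries and 2.85 without L3 library 2. Among 3 tested neuroblast and progenitor markers 1 fell (1 adjusted over the list alone). This was E(spl)mgamma-HLH, from 41.0 CPM to no count, at least 56.6-fold, with L3 libraries at 67.4 and 14.6 CPM. That call was lost without L3 library 1 (adjusted p = 0.101), and 2 progenitor markers fell without L3 library 2 or adult library 1, 2 or 3. insc was at 55.0 and 31.8 CPM, with a neighbour's counts.

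Of 3 tested hemocyte markers, 1 rose (1 adjusted over the list alone). Hml, hemolectin, rose from 32.3 ± 11.1 to 1278 ± 297 CPM (log2 fold change 5.22, SE 0.47, adjusted p = 8.35e-08). NimC1 and He stayed at or under 6.21 CPM in every adult library. Among 2 tested fat body markers, Lsp1beta fell from 25.5 to 0.548 CPM, a pooled-count ratio of 50.4 with a counting interval of 13.6 to 421, and Yp2, which shared counts, rose from 3.85 to 37.3 (1 and 1 adjusted over the list alone). The rise of Yp2 was lost without L3 library 1 (adjusted p = 0.115) or L3 library 2 (adjusted p = 0.0594). Of 7 photoreceptor markers, 2 rose, norpA among them, and 0 fell (2 and 1 adjusted over the list alone), with camera at 0.648, and 0.748 with an estimated correlation. Of these, 0 rose without L3 library 1, L3 library 2 or adult library 4, and 1 without adult library 1. inaD, with the counts of RpL23, was at 1082 and 610 CPM and fell without L3 library 2 (adjusted p = 0.0103) or adult library 3 (adjusted p = 0.0177). The muscle marker Mlc2, with neighbours' counts, was at 3.31 and 17.1 CPM (1 rose adjusted over the list alone) and passed without adult library 3 (adjusted p = 0.0375).

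**Figure D3:**
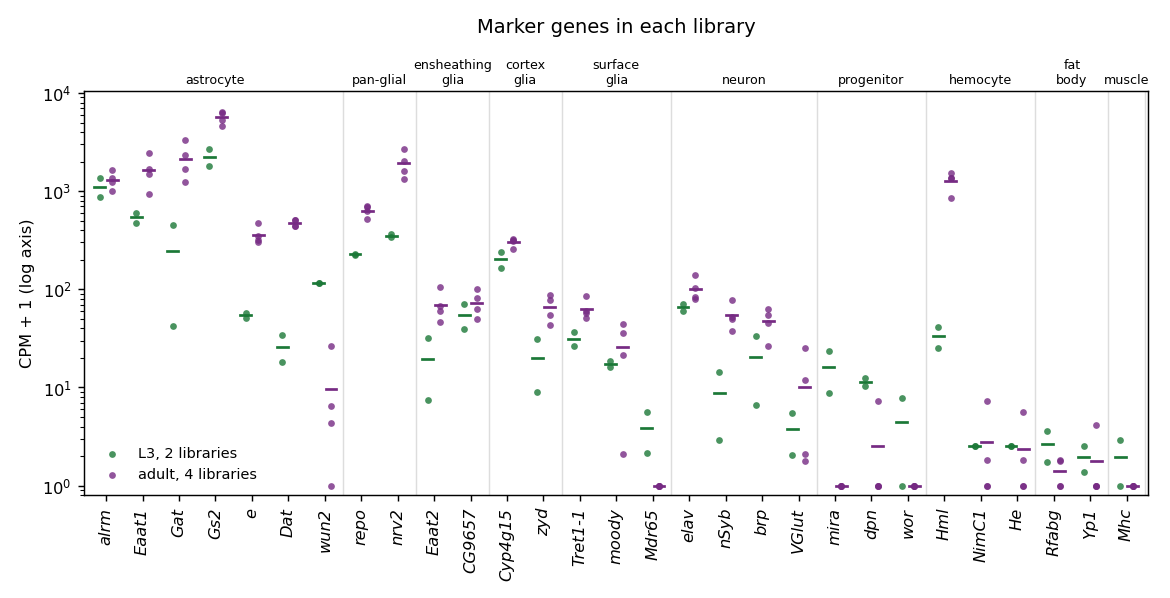
CPM plus 1 on a log axis for marker genes in each library, with L3 libraries in green, adult libraries in purple and the stage mean as a bar. alrm was at 1103 and 1305 CPM, and Hml, a hemocyte gene, at 32.3 and 1278 CPM.

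Of 29 tested genes for transmitter and ion handling, 21 rose and 2 fell (23 and 2 adjusted over the list alone). This list shares Eaat1, Gat, Gs2, e and Dat with the astrocyte markers, and nrv2, Eaat2 and zyd with other glial marker lists. Its rise and that of the astrocyte markers are therefore not separate results. CAH1, a carbonic anhydrase with the same counts as Rat1, rose from 276 ± 46.0 to 2727 ± 262 CPM (log2 fold change 3.29, SE 0.36). The gap junction gene Inx2 rose from 277 to 723 CPM, the sodium pump gene Atpalpha from 154 to 489 and the TRP channel gene wtrw from 8.80 to 141. The glutamate dehydrogenase gene Gdh, which shared counts with CG5854 and nearly those of RpS19b, fell from 157 to 8.89 CPM (log2 fold change -4.12, SE 0.51), and nrv1 was the other fall. Camera gave the list an adjusted p of 5.46e-08, and adjusted p = 0.366 with an estimated correlation. The neuron marker list had a camera adjusted p of 0.00269, and 0.366 with an estimated correlation, and nSyb rose from 7.71 to 53.5 CPM, so a share of neuronal RNA in the adult pools was not ruled out. With L3 library 1 left out, the median log2 fold change was 1.59 for the transmitter and ion list and 1.49 for the neuron list. Without L3 library 2 these medians were 2.50 and 2.85, and with all libraries 1.84 and 1.67. Both lists therefore depended on which L3 library was kept. The earlier quasi-likelihood method gave 12 rises and 2 falls for the transmitter and ion genes, and 10 and 1 of 22 tested with 1 row per group as well.

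Actin genes, the subject of the series' title, moved in both directions. Of 51 tested genes of the actin cytoskeleton and its regulators, 6 rose and 10 fell (6 and 11 adjusted over the list alone). Actin genes themselves differed in direction. Act42A fell from 220 ± 53.6 to 12.9 ± 13.6 CPM (log2 fold change -4.40, SE 0.58), Act5C from 358 to 97.7 CPM, and the profilin gene chic, which shared counts with neighbours, from 1427 ± 458 to 358 ± 30.9 CPM. Act79B, an actin gene outside the list, chosen after its values were seen, rose from 2.08 to 323 CPM (log2 fold change 6.97, SE 0.75). Only 1 of 9 muscle markers could be tested, so muscle RNA as a source of Act79B was not examined. The rises in the list included the Rac-family GTPase gene Mtl, from 14.1 to 109 CPM (log2 fold change 2.98, SE 0.56), the myosin gene jar, from 81.1 to 322 CPM, and RhoGEF2, from 55.6 to 266 CPM. Rac1 was at 137 and 108 CPM (adjusted p = 0.510). RhoGEF64C went from 931 to 32.2 CPM, but its counts differed from those of Hsp27 by only 4.12% of their sum and from those of Hsp23 by 4.43%. Camera did not call the list (adjusted p = 0.452, and 0.635 with an estimated correlation). Only 5 rose and 5 fell without L3 library 1.

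Cell adhesion and axon guidance genes mostly stayed under the threshold. Of 41 tested, 3 rose and 11 fell (3 and 11 adjusted over the list alone). The immunoglobulin-family gene bdl rose from 64.9 ± 19.0 to 1108 ± 160 CPM (log2 fold change 4.02, SE 0.41, adjusted p = 3.39e-07), and kirre from 36.4 to 137 CPM. The netrin receptor gene unc-5 fell from 186 to 11.8 CPM, the Slit receptor gene robo2 from 53.3 to 2.35 and the integrin gene mys from 75.2 to 12.2, all 3 with neighbours' counts. Camera did not call the list (adjusted p = 0.142, and 0.575 with an estimated correlation). When L3 library 1 was omitted, 2 rose and 7 fell and camera called the list lower (adjusted p = 0.0169). The earlier quasi-likelihood method gave 2 rises and 3 falls, and the stricter filter 3 and 3 of 24 tested.

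Of 20 tested extracellular matrix genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone). The collagen IV genes Cg25C and vkg, the perlecan gene trol and the cell-surface glypican gene dally rose. The laminin gene LanB1, also of the basement membrane, fell. trol went from 3.66 ± 1.44 to 266 ± 30.8 CPM (log2 fold change 6.16, SE 0.58), dally from 11.6 to 355, and vkg, with the counts of CG3887, from 65.9 to 799. The laminin gene LanB1 fell from 34.2 CPM to no count, at least 47.3-fold, and dlp and Mmp2, each with neighbours' counts, fell from 41.5 to 7.10 CPM and from 46.6 to 12. Camera gave an adjusted p of 0.186, and 0.366 with an estimated correlation. The number that fell was 2 without L3 library 1.

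Of 25 tested genes of engulfment and the JNK pathway, 2 rose and 6 fell (3 and 6 adjusted over the list alone). The engulfment adaptor gene ced-6, with the counts of Pdk, rose from 64.5 ± 25.0 to 323 ± 47.8 CPM. The Fos gene kay, with the same counts as CG3817, fell from 238 to 61.1 CPM, and prtp and CaBP1, each with a neighbour's counts, fell from 891 to 217 and from 125 to 20.4. The engulfment receptor gene drpr, with the counts of CG7991, was at 108 and 66.6 CPM (adjusted p = 0.204). Camera did not call the list (adjusted p = 0.523, and 0.635 with an estimated correlation). The number that rose was 1 without L3 library 1 or adult library 4, and 4 without adult library 3.

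Among 22 ecdysone response genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone). ImpE1 fell by 5.88 on the log2 scale (SE 0.47), and br, a transcription factor of metamorphosis, fell from 35.8 to 0.336 CPM, a pooled-count ratio of 136 with a counting interval of 24.1 to 5413. E23, a transporter, rose from 23.5 to 92.3 CPM, and this was lost without L3 library 1 (adjusted p = 0.131). The receptor gene EcR was at 67.9 and 31.4 CPM (adjusted p = 0.108). Of 7 developmental timing regulators, 1 rose and 2 fell (1 and 2 adjusted over the list alone): ab, with the counts of cmet, rose to 202 CPM in adult (adjusted p = 8.76e-06), and br and let-7-C, the latter with neighbours' counts, fell. Only 1 fell without L3 library 1 or 2 or adult library 1, 2 or 3. Camera called neither list (adjusted p = 0.623 and 0.962, and 0.635 and 0.980 with an estimated correlation).

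Signalling lists also went both ways. Of 16 tested genes of FGF and EGF receptor signalling, 3 rose and 2 fell (5 and 2 adjusted over the list alone), with a median log2 fold change of -0.21, a mean of -0.08 and an upward camera direction (adjusted p = 0.661, and 0.831 with an estimated correlation). The pathway inhibitor gene sty rose from 215 to 601 CPM. The leucine-rich repeat gene kek1 fell from 114 to 8.89 CPM and Ras85D from 81.7 to 15.4. Omitting L3 library 1 left 0 rises and 1 fall, with adjusted p = 0.152 for sty and 0.101 for Ras85D, and sty was also lost without adult library 4 (adjusted p = 0.0513). Of 15 Notch pathway genes, 1 rose and 6 fell (2 and 7 adjusted over the list alone). The Notch target gene E(spl)malpha-BFM fell from 33.6 to 1.05 CPM, E(spl)mbeta-HLH, with the counts of CR45038, from 104 to 27.5, and the coactivator gene mam, with the counts of Prosap, rose from 44.2 to 181. Camera gave the Notch list an adjusted p of 0.0855, and 0.500 with an estimated correlation. It called the list lower without L3 library 2 (adjusted p = 0.00195) or adult library 4 (adjusted p = 0.0445). Of the Notch genes, 0 rose and 1 fell without L3 library 1, with adjusted p = 0.0913 for mam and 0.460 for E(spl)mbeta-HLH. Without adult library 1, 2 rose and 4 fell, without adult library 3, 2 rose and 3 fell, and without adult library 2, 3 fell.

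Of 35 tested cell cycle and replication genes, 1 rose and 13 fell (1 and 15 adjusted over the list alone). The kinase gene Cdk4 fell from 499 ± 238 to 85.7 ± 27.3 CPM (log2 fold change -2.60, SE 0.39), the clamp gene PCNA, with the counts of Hsl, from 108 to 14.2 CPM, and CycB from 41.2 CPM to no count, at least 56.9-fold. Orc2 is among the falls and has nearly the counts of RpL4. Cdk1 rose from 105 to 262 CPM, which was lost without L3 library 1 (adjusted p = 0.0575) or L3 library 2 (adjusted p = 0.156). Camera called the list lower (adjusted p = 0.000465, and adjusted p = 0.366 with an estimated correlation). With L3 library 1 omitted, 0 rose and 8 fell. The earlier quasi-likelihood method also gave 0 and 8, or 0 and 5 of 23 tested with 1 row per group, and the stricter filter 1 and 4 of 21 tested. The progenitor marker mira, too low to be tested, was at 15.3 CPM in L3 and had no count in adult.

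Most ribosomal protein genes fell. Of 86 tested, 1 rose and 53 fell (1 and 66 adjusted over the list alone), with a median log2 fold change of -1.08. RpLP0 fell from 1283 ± 426 to 345 ± 127 CPM (log2 fold change -1.96, SE 0.35), RpS5a, with neighbours' counts, from 1357 to 354 CPM, and RpS19b, with neighbours' counts and nearly those of Gdh, from 139 to 8.30. RpL22, with neighbours' counts, rose from 1572 to 3445 CPM, which was lost without L3 library 2 (adjusted p = 0.0754) or adult library 1 (adjusted p = 0.0510). Of the 86 genes, 75 shared counts with neighbours. Camera called the list lower (adjusted p = 6.16e-07, and adjusted p = 0.564 with an estimated correlation). The number that fell was 13 without L3 library 1, 33 without adult library 1 and 35 without adult library 4.

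Of 23 tested genes of glycolysis and sugar transport, 4 rose and 2 fell (4 and 2 adjusted over the list alone). The trehalase gene Treh, with the counts of Rbpn-5, rose from 209 to 2207 CPM (log2 fold change 3.42, SE 0.39). The hexokinase gene Hex-A rose from 3.05 to 126 CPM and the aldolase gene Ald from 428 to 1148. Pepck fell from 26.4 to 3.84 CPM, lost without L3 library 1 (adjusted p = 0.486), adult library 1 (0.106), adult library 2 (0.0932) or adult library 4 (0.124). Camera gave an adjusted p of 0.00478, and adjusted p = 0.366 with an estimated correlation. No member fell without L3 library 1 or adult library 1 or 4, and 1 fell without L3 library 2 or adult library 2 or 3.

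Of 69 tested genes of the mitochondrial respiratory chain, 2 rose and 3 fell (1 and 2 adjusted over the list alone), with a median log2 fold change of 0.36, and 0.61 without L3 library 1. Cyt-c-p, a cytochrome c gene that shared counts with VhaSFD, rose from 127 to 534 CPM. ox, with neighbours' counts, fell from 721 to 182 CPM. ATPsynbetaL fell from 26.1 CPM to no count, at least 36.1-fold, with L3 libraries at 11.7 and 40.6 CPM, and its call was lost without L3 library 2. ND-MNLL, with the counts of RpS6, fell from 1897 to 1010.1 CPM, lost without L3 library 1 (adjusted p = 0.525), adult library 1 (0.127), adult library 2 (0.131) or adult library 4 (0.139). Camera called the list higher (adjusted p = 0.00269, and adjusted p = 0.564 with an estimated correlation). The number that rose was 1 without L3 library 1 or 2, or adult library 2 or 4.

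Few lipid and lysosomal genes passed the test. Of 29 tested lipid genes, 3 rose and 2 fell (2 and 2 adjusted over the list alone), with a median log2 fold change of 0.17, a mean of -0.04 and an upward camera direction (adjusted p = 0.962, and 0.980 with an estimated correlation). The lipoprotein receptor gene LpR2 rose from 4.54 to 33.8 CPM, the lipase gene bmm from 2.70 to 26.2, and scu, a mitochondrial dehydrogenase gene, fell from 131 to 49.7. Leaving out L3 library 1 gave 0 rises and 1 fall, with adjusted p = 0.116 for LpR2, 0.157 for bmm and 0.0686 for scu. The counts were also 0 and 1 without L3 library 2, with 0.107, 0.0992 and 0.120, and without adult library 4 they were 1 and 1, with 0.0733 for bmm and 0.0712 for scu. Lip4 fell from 70.2 to 2.71 CPM with the same counts as Cyp4ac2 and Cyp4ac3.

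Of 39 tested genes of autophagy, lysosome and proton pump, 5 rose and 1 fell (3 and 0 adjusted over the list alone). VhaSFD rose with the counts of Cyt-c-p, Vha68-1, with the counts of CG12404, from 15.1 to 52.9 CPM and LManI from no count to 13.6 CPM, at least 20.7-fold, while Vha68-2 fell from 77.9 to 28.2. The counts were 1 and 0 without L3 library 1, and 2 and 0 without adult library 4. Vha68-1, LManI and Vha68-2 were each lost without L3 library 1 (adjusted p = 0.235, 0.164 and 0.138), L3 library 2 (0.0550, 0.113 and 0.192) or adult library 4 (0.0572, 0.0546 and 0.158). Vha68-2 was also lost without adult library 2 (0.0852) or adult library 3 (0.0526). Camera gave an adjusted p of 0.118, and 0.366 with an estimated correlation.

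Of 22 tested heat shock and stress genes, 0 rose and 10 fell (0 and 12 adjusted over the list alone). Of the 22 genes, 18 shared counts with neighbours, and only 3 of the 10 falls were of genes that did not. Hsp23 fell by 5.30 on the log2 scale (SE 0.43), Hsp27 from 859 ± 16.5 to 34.4 ± 45.4 CPM, and Hsp67Ba from 53.3 to 6.15. The counts of Hsp23 and Hsp27 differed by 6.09% of their sum. The chaperone genes Hsp83 and Hsc70-4, each with a neighbour's counts, fell from 1075 to 272 CPM and from 1462 to 418. Camera called the list lower (adjusted p = 0.00269, and adjusted p = 0.366 with an estimated correlation). The number that fell was 5 without L3 library 1.

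Of 11 tested genes of the circadian clock and its outputs, 4 rose and 1 fell (4 and 1 adjusted over the list alone). Besides tim (log2 fold change 7.94, SE 0.65), Pdp1 rose from 13.3 ± 6.98 to 568 ± 178 CPM, the photoreceptor gene cry from 2.55 to 55.1 and Clk from 0.189 to 22.2, a pooled-count ratio of 107 with a counting interval of 18.7 to 4264. per, at 3.12 and 0.468 CPM, was too low to be tested, and vri, with the counts of CG14024, was at 75.3 and 64.4 CPM (adjusted p = 0.755). CkIIbeta, with the counts of Hsc70-3, fell from 494 to 209 CPM, lost without L3 library 1 (adjusted p = 0.250), where 3 of the list rose and 0 fell. Camera called the list higher (adjusted p = 0.00478, and adjusted p = 0.366 with an estimated correlation). The sample titles do not give the time of day of collection, and its part in these values was not tested.

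Of 20 tested antimicrobial and immune genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone). The Toll ligand gene spz, with neighbours' counts, fell from 57.7 to 0.971 CPM. PGRP-LA rose from 5.98 to 61.9 CPM with the same counts as the distant gene MYPT-75D, and PGRP-SC2, with neighbours' counts, rose from 44.7 to 129, lost without L3 library 2 (adjusted p = 0.176). PGRP-SC1a fell from 140.0 to 40.6 CPM, lost without L3 library 1 (adjusted p = 0.0850), and its counts differed from those of the distant gene Prosalpha5 by 10.4% of their sum. Camera gave an adjusted p of 0.186, and 0.366 with an estimated correlation. The counts were 2 and 1 without L3 library 1, 1 and 2 without L3 library 2 and 3 and 2 without adult library 4.

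Of 72 tested detoxification genes, 14 rose and 10 fell (15 and 10 adjusted over the list alone). Besides the Ugt35b group, the superoxide dismutase gene Sod3, with the counts of Tsp47F, rose from 18.7 to 464 CPM and GstE2 from 25.1 to 251. GstS1, with the counts of CG6984, fell from 166 to 33.1 CPM. Camera gave an adjusted p of 0.134, and 0.366 with an estimated correlation. These counts were 10 and 6 without L3 library 1.

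Of 8 sex-dependent transcripts, 3 rose and 1 fell (4 and 1 adjusted over the list alone). fru, with the counts of CG10864, rose from 32.1 to 192 CPM, and the dosage compensation RNA roX2, with the same counts as CG12239, from 21.5 to 140.1. tra, with neighbours' counts, fell from 431 to 180 CPM, lost without L3 library 1 (adjusted p = 0.237), where 1 rose and 0 fell. Camera gave an adjusted p of 0.155, and 0.366 with an estimated correlation. The labels do not give the sex of the animals.

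**Figure D4:**
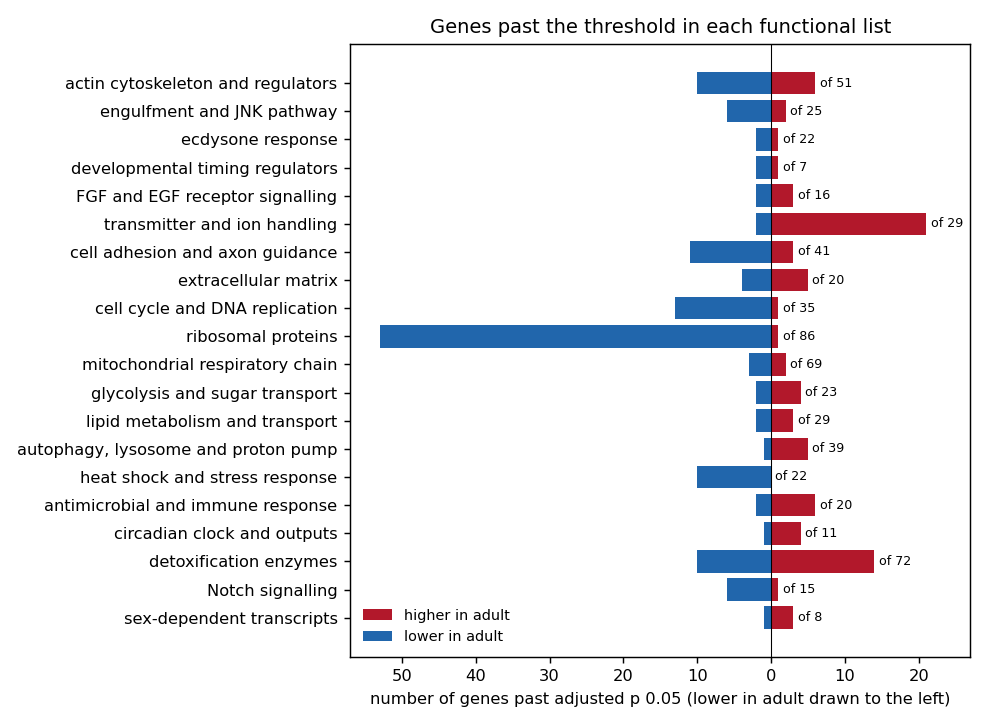
Number of genes past adjusted p 0.05 in each functional list, with genes higher in adult drawn to the right in red, genes lower drawn to the left in blue, and the number tested beside each bar. The longest bars are 21 of 29 rises for transmitter and ion handling and 53 of 86 falls for ribosomal proteins.

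Calls in these other lists were also fewer with the earlier quasi-likelihood method. Rises and falls were 5 and 1 for extracellular matrix, 4 and 0 for glycolysis, 1 and 2 for the respiratory chain, 0 and 1 for lipid genes, 1 and 0 for autophagy, 1 and 1 for immune genes, 11 and 6 for detoxification and 1 and 2 for Notch genes. They were 1 and 2 for FGF and EGF receptor signalling, 1 and 5 for engulfment, 0 and 2 for ecdysone response, 1 and 1 for timing regulators and 4 and 7 for actin genes. For markers they were 1 and 0 for neurons and cortex glia and 0 and 0 for photoreceptors, ensheathing glia and surface glia. Ribosomal protein genes gave 1 and 38, or 0 and 15 of 47 tested with 1 row per group.

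Across the 25 lists tested with camera, 6 were higher and 3 lower in adult, and 0 were called with an estimated correlation. In fry's two-way test, which asks whether members change in either direction, 23 lists passed. No list's median moved when genes with no count in 1 stage were set to their bound. This says little, because many lists had 0 such members and the cell cycle list, with the most, had 5.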

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

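The tests of shared counts below were chosen after the near-identical counts had been seen. Among 101 sets of values over the 4 adult libraries (library totals and levels of named genes), 14 had 1 library far from the other 3 by Dixon's ratio. Chance gives about 1 in 20, or 5.05, for continuous values. That rate does not hold for 7 of the 14, whose other 3 libraries had no count, because any count then gives the highest ratio. Groups as small as the L3 pair were not tested.

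Several of these values were a few counts in 1 library against none in the other 3. They were 0.776 CPM of ppk30 and of Obp99a, which share counts, in adult library 4, 3.88 CPM of spz in adult library 4, 1.34 CPM of br and 9.39 CPM of robo2 in adult library 2, 15.3 CPM of Pepck in adult library 3 and 10.9 CPM of Lip4 in adult library 1. In adult library 4, nrv1 was at 7.76 CPM against 0 to 1.10 in the others, RhoGEF64C at 97.1 against 4.38 to 17.4 and Hsp27 at 102 against 4.38 to 20.9. In adult library 2, ImpE1 was at 34.9 CPM against 5.44 to 10, tra at 106 against 193 to 210.4, and LpR2 at 1.34 against 42.7 to 46.8. In adult library 3, ND-MNLL was at 1515 CPM against 787 to 898.

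Near-identical counts were found for neighbouring genes and between genes far apart. The same reads may have been counted for more than 1 gene: near-identical counts were 6.84 percentage points more frequent among genes at most 10 rows apart than among genes far apart. Of 4505 shared pairs with both genes in the reference, 4491 (99.7%) were neighbours there. Separate transcripts of neighbours that are regulated together would differ by counting noise, but 50.7% of the near-identical pairs (2315 of 4569) had exactly equal counts in all 6 libraries. Reads counted for distant genes would explain the 159 distant pairs, and how the deposited counting assigned reads was not given in the sources used here.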

How the results depend on the processing

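Added after the data were seen were the earlier quasi-likelihood method, 1 row per group of genes that share counts, both together, and the 4 libraries of the block fit without a block. Genes higher and lower in adult numbered 876 and 1188. They were 403 to 1020.0 and 509 to 1189 when each library was left out in turn, 521 and 558 with the earlier method, 542 and 716 with 1 row per group, 325 and 294 with both (6032 rows tested in these), and 512 and 648 at a threshold of 0.01. DESeq2 called 673 lower. The cause was not tested, apart from fewer rows, fewer libraries and the stricter threshold by construction. The remaining settings, apart from the block below, kept both counts within 1.5 times. Only without L3 library 1 (1 gene) and without L3 library 2 (3 genes) did a called gene change sign. The median log2 fold change was -0.14, and ran from -0.43 with voom to -0.04 with at least 10 counts in 4 libraries.

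Same-numbered libraries showed no clear pairing, as their deviations from the stage means correlated at -0.009 and 0.024. Adult libraries 3 and 4, which have no L3 library of their number, reached 0.124 with L3 library 1 and 0.113 with L3 library 2. The deviations of the 2 L3 libraries mirror each other, so all these values rest on 1 contrast. A shared day or batch is therefore not excluded. With the number as a block on 4 libraries, 306 genes were higher and 186 lower, against 779 and 885 on the same libraries without the block.

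Lists called numbered 6 higher and 3 lower, 0 and 0 with an estimated correlation, with 6 and 5 by fry and 5 lower of 29 tested with no filter. The higher lists of fry were not the same: neurons (0.0884) and the mitochondrial respiratory chain (0.189) were lost, and extracellular matrix (0.0143) and detoxification (0.0268) were gained. Its lower lists gained ecdysone response (0.0282) and Notch signalling (0.0392), and camera called Notch signalling lower with no filter (0.00763), as it did progenitor markers (0.00249), and with the replicate block (0.0264). The medians of pan-glial, engulfment, extracellular matrix, immune and detoxification genes changed sign in at least 1 setting while the direction of the test did not. The test changed direction for 3 other lists that camera did not call, whose medians follow. For developmental timing regulators they were -0.11 with no filter and -0.91 to 2.50 as each library was left out (2.50 without L3 library 2). For FGF and EGF receptor signalling they were -0.21 with fry, -0.47 with no filter and -0.43 to 0.14 as each library was left out. For lipid genes they were 0.17 with fry, -0.49 with no filter, -0.18 to 0.26 as each library was left out, -0.44 with the replicate block and 0.16 with 1 row per group. The cause was not tested. Of 90 named genes called, 46 kept the call in every setting that tested them. Another 44 lost it in at least 1 setting, 39 of them with the replicate block, and 0 changed sign. A gene that a setting did not test counted as kept there, and the threshold of 0.01 was not applied to these genes. Depth limits adult values, since the shallowest library held 745129 counts, and 400250 with 1 row per group of genes that share counts. With all libraries thinned to 745129 counts, 681 and 885 genes were called.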

Other observations

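The 5 tests of other cell types for Hml and the matrix genes were chosen after those values had been seen, and both cell cycle tests were written before their results. Some large changes lay outside the lists, in genes that shared no counts by the search used here, chosen after their values were seen. CG9394 rose from 8.82 ± 1.44 CPM in L3 to 6853 ± 1637 in adult (log2 fold change 9.53, SE 0.60). CG12991 rose from 3.03 to 149 CPM. CR43264, a noncoding RNA, fell from 984 to 1.19 CPM. Tep4, a thioester-containing protein gene, fell from 77.8 to 1.45 CPM, and Idgf4, an imaginal disc growth factor gene, from 183 to 6.71.

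Hml and the matrix genes Cg25C, vkg, trol and dally, grouped after they were seen to rise, each had a log2 fold change that, less its SE, was at least 3.16, while the laminin gene LanB1 fell. Hemocytes in the adult sorts would bring NimC1, He, eater and srp, which together reached at most 1.51% of the Hml CPM in any adult library, but with Pxn and crq added the sum reached 5.14% to 10.6%, so hemocytes are left open. Fat body would bring its markers, but Rfabg, Yp1 and Yp3 together reached at most 0.296% of the Cg25C CPM. All 10 listed markers, with Yp2, reached at most 3.23%. Yp1, Yp2 and Yp3 were also listed as sex-dependent, and sex was not given, so their small share cannot exclude fat body. Surface glia would raise their markers alike if the L3 pools held few of them, but the highest tested marker reached a log2 fold change, with its SE added, of 2.66. Tret1-1 was already at 30.5 CPM in L3, and 4 of the 6 tested markers shared counts with neighbours. This test therefore cannot exclude surface glia. A difference between larval and adult astrocytes remains a hypothesis, and the longer enzyme time of adult brains could not be separated from stage.

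13 cell cycle genes fell in adult, where libraries were shallower. Lower depth would have ended most calls in thinned libraries, but 9 of the 13 falls were still past the threshold, with 11 tested. Progenitor cells in the L3 sorts may account for part of the pattern, because dpn, mira, ase, wor, klu and nab summed to 56.4 and 26.5 CPM in the L3 libraries and 1.55 on average in adult. With no filter on low counts, camera at the preset correlation called the progenitor list lower (adjusted p = 0.00249). An estimated correlation was not run in that setting. The mean log2 ratio of L3 library 1 to 2 was 1.28 (SE 0.55) for these 6 progenitor markers (insc and E(spl)mgamma-HLH were left out, and grh and tap had too few counts) and 0.45 (SE 0.14) for the 13 cell cycle genes, a difference of 0.83 (SE 0.57) that leaves this explanation open with 2 L3 libraries. The SEs of these ratios are over genes within 1 contrast of 2 libraries, so they do not measure spread between libraries. Of the 13 falls, 8 were of genes that shared no counts with neighbours, and Orc2 had nearly the counts of RpL4. Division of larval astrocytes was not tested.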
